A study of Homo sapiens with 12 samples.

How the data were processed

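Gene expression was measured with Illumina bead arrays in Caco-2 cells, a human colorectal adenocarcinoma epithelial line, on 12 arrays in 5 groups. Per the labels' protocols, cells received a plasmid expressing SIRT1 or an empty vector, or 1 of a pair of SIRT1 siRNAs or a scrambled siRNA. The siRNA cells were lysed after 72 h; the time of lysis after plasmid transfection was not given in the sources used here. Total RNA was extracted with Trizol and a column kit and turned into biotin-labelled cRNA. Per the submitters' processing notes, the arrays were read with GenomeStudio 2010.1.

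The authors deposited raw probe intensity values for 47323 probes, with no normalization and different medians per array. Beside each intensity the deposited tables hold a detection p-value, stored as 1 minus p: the rank correlation of this column with intensity was at least 0.985 on each array. The deposited normalised values are on a log2 scale and share 1 distribution across arrays, to within 0.02; the normalization method was not given in the sources used here. The value table deposited with the series holds 47231 of these probes, with values equal to the normalised table (largest difference 0). None of the other 92 probes was detected on any array.

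Raw intensities of the 47231 probes were background-corrected from the detection p-values and quantile-normalised to log2 with neqc (limma 3.58.1 in R 4.3.3, offset 16) across the 12 arrays. Probes with a detection p below 0.01 on at least 2 arrays were kept, which left 19263. Of these, 15104 had 1 gene symbol in the platform annotation and 4159 had no single symbol. Symbols were checked through Entrez identifiers against a RefSeq gene table, used for names alone, which changed 0 of them. For each gene the probe with the highest mean level was used, giving 11458 genes; 2946 of these had more than 1 passing probe. The array files name no genome build, so no positions are given. The number of arrays, 2 or 3 per group, limits the precision: the median standard error of a log2 fold change was 0.14 for overexpression and 0.17 for each siRNA.

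All 12 arrays entered 1 limma fit with a mean for each group (7 residual degrees of freedom, prior 3.74), and every p for a gene is from limma's moderated test, two-sided. The fit assumes 1 variance per gene for all groups, although spread differed. The score of the hypoxia list, defined below, ranged over 1.29 within KD1 and 0.80 within KD2, against 0.06 to 0.22 within the other groups. An SE between 2 groups therefore also reflects arrays of the other groups. For LOX the SDs were 0.18 in the scrambled and 0.07 in the vector controls, but the SE between them was 0.50. P-values were adjusted over genes by Benjamini and Hochberg, with a threshold of 0.05. The comparisons were overexpression against vector, each siRNA against scrambled siRNA, the mean of both siRNAs against scrambled siRNA, the siRNAs with each other, and the scrambled siRNA against the vector. A fixed set of 46 gene lists was tested with camera (limma, preset correlation 0.01) where at least 5 members were tested, which held for 43 lists; p-values were adjusted over lists. An estimated correlation per list and fry, which tests whether the genes of a list move on balance one way, were run beside it. List scores per array are means of the members' levels after centring each gene. The mean over arrays of a group is given with its SD, and log2 fold changes with their SE.

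Genes named in the text were taken by rule: up to 10 genes with the highest and 10 with the lowest log2 fold change among those past the threshold whose groups did not overlap, with 1 symbol that is not a placeholder; where none passed, the 5 smallest unadjusted p in each direction; for the siRNAs against each other and the controls against each other, 5 in each direction. List members were named by fold change among those past the threshold, or by smallest p where none was. SIRT1 was always named. For a gene not detected in any array of a group, the fold is given as a lower bound, with each array of that group set to the lowest level of a detected probe on it, or to its own level where that is higher. Genes named because a count held 5 or fewer (EPG5, BIRC7, TNFSF10, IGFBP6, ALOX5AP, BRWD3, SLC39A2 and CIAO2A) were chosen after their values were seen. The groups, comparisons, tests, gene lists, naming rule and most alternative settings were fixed before the data were examined. A covariate for the hypoxia score, a scaling without quantiles and the count of called genes that also differed between the controls were added after the data had been seen.

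The pipeline was tested on simulated data of the same size, with 200 of 11458 genes changed in each of 20 simulations. It recovered 34.4% of 1.5-fold, 79.7% of 2-fold and 96.5% of 3-fold changes in the overexpression design, and 7.23%, 67.2% and 91.5% for the first siRNA. Of the calls, 4.32% to 9.03% were false over the designs and folds tried. Noise was drawn independently for each gene with the same SD in all groups, so recovery on the real arrays may differ. A simulation of 100 data sets without change gave the similarity that shared controls produce between the siRNAs if spread is equal across groups. Alternatives were the deposited normalised table, no background correction, normexp with offset 50, each experiment normalised separately, no filter or a stricter filter, each experiment's arrays alone, a trend and robust variance model, all probes, a fold threshold of 1.5, a replicate block, and leaving out each array. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.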

Results

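The 12 arrays measured RNA levels in Caco-2 cells, a human colorectal adenocarcinoma line used as a model of gut epithelium, after treatments meant to raise or lower SIRT1. SIRT1 is an NAD-dependent protein deacetylase. The groups were a vector control (OE control, n = 3), SIRT1 overexpression (OE Sirt1, n = 3), a scrambled siRNA control (n = 2) and the SIRT1 siRNAs KD1 (n = 2) and KD2 (n = 2). The KD2 arrays carry the replicate numbers 2 and 3. Between 15345 and 17981 probes were detected per array (32.5% to 38.1%), and raw median intensities ran from 108.6 to 152.6. Pearson's r across genes between arrays ran from 0.961 to 0.992. The first principal component held 44.3% of the variance and separated the plasmid arrays (all at or below -14.3) from the siRNA arrays, of which KD1 replicate 1, at -1.92, was the lowest. The array nearest to KD1 replicate 1 was a plasmid array, OE Sirt1 3 (r = 0.990), and its mean r was 0.987 with the plasmid arrays, 0.983 with the other siRNA arrays and 0.984 with the other KD1 array.

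SIRT1 RNA fell with both siRNAs, and its probe did not differ detectably with the overexpression plasmid. Its mean log2 level was 8.69 ± 0.21 (SD, n = 2) in the siRNA controls, 7.30 ± 0.02 (n = 2) with KD1 and 7.48 ± 0.49 (n = 2) with KD2. The log2 fold change was -1.39 with KD1 (SE 0.22, limma adjusted p = 0.0468), 2.62-fold lower, and -1.20 with KD2 (SE 0.22, adjusted p = 0.0492), 2.31-fold lower. The mean of both siRNAs gave -1.30 (SE 0.19, adjusted p = 0.0243). In the plasmid arrays the level was 8.65 ± 0.09 (n = 3) with OE Sirt1 and 8.65 ± 0.24 (n = 3) with vector, a log2 fold change of -0.00311 (SE 0.18, 95% interval -0.40 to 0.39, adjusted p = 1). The array carries 1 SIRT1 probe, and whether it lies within the transfected sequence is not known from the sources used here. The KD1 call was lost at -1.39 with the replicate block (adjusted p = 0.12), on the siRNA arrays alone (0.434) and without a detection filter (0.0695), at -1.51 with the hypoxia covariate (0.0577), and at -1.54 without siRNA control 1 (0.258), -1.24 without control 2 (0.356), -1.40 without KD1 replicate 1 (0.199) and -1.38 without replicate 2 (0.128). The KD2 call was lost at -1.20 on the siRNA arrays alone (0.274) and without a filter (0.0735), at -1.35 without siRNA control 1 (0.169), -1.06 without control 2 (0.299) and -0.86 without KD2 replicate 3 (0.17), but not without KD2 replicate 2 (0.0203).

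**Figure D1:**
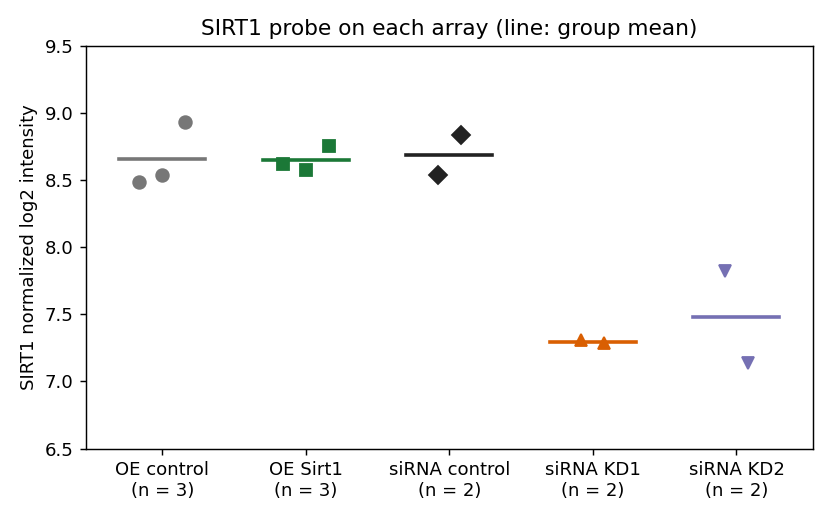
SIRT1 log2 level (y axis) on each of the 12 arrays by group (x axis), with a line at each group mean. The 4 SIRT1 siRNA arrays lie at or below 7.83, and the 8 other arrays lie between 8.49 and 8.93.

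The question of the overexpression arrays was which genes change when SIRT1 is supplied from a plasmid. No gene passed: limma called 0 of 11458 genes, the smallest adjusted p was 0.552, and 407 genes had an unadjusted p under 0.05 (239 higher, 168 lower) against 573 expected by chance. The genes nearest to a call in the higher direction were NTS, the gut peptide neurotensin, VPS9D1, TSPAN12, CROT, a peroxisomal carnitine transferase, and MRPS31P5. VPS9D1 stood at +0.71 (SE 0.13). The others were not detected on any of the 3 vector arrays. TSPAN12 was at least 1.18-fold and CROT at least 1.27-fold higher, the other TSPAN12 probe stood at +0.12, and NTS allowed no bound. MRPS31P5 was detected on 2 of 3 OE Sirt1 arrays, so its 1.05-fold by this rule is no firm bound. In the lower direction they were TERC, the RNA template of telomerase (-0.72, SE 0.12), ISM1 (-1.02, SE 0.21, detected on 1 of 3 OE Sirt1 arrays), MAP3K5, a stress kinase, KRTAP10-11 and PPIAL4G. The last 3 were not detected on any OE Sirt1 array. MAP3K5 and KRTAP10-11 were at least 1.33-fold and 1.52-fold lower. PPIAL4G was detected on only 1 of 3 vector arrays, so its 1.14-fold by this rule is no firm bound. Among the gene lists 1 of 43 passed: type I interferon response genes lay lower, with a mean log2 fold change of -0.10 over 25 genes, 21 of them below 0 (camera adjusted p = 0.00794, adjusted p = 0.762 with an estimated correlation, fry 0.93). None of its members passed over all genes or adjusted over the list alone, and OAS1 stood at -0.35 and HERC6 at -0.25. The list call was lost without OE control 1 (adjusted p = 0.525), OE Sirt1 1 (0.0663) or OE Sirt1 3 (0.0541). Leaving out OE Sirt1 replicate 3 brought 1 gene, EPG5, past the threshold. With the replicate number as a block 0 genes passed. To look for pairing, group means were removed from each gene. The remaining values of same-numbered arrays were not alike (r = -0.166, -0.112 and 0.0323 across genes), so the numbers gave no pairing. The highest such r between a vector and an OE Sirt1 array was 0.226, for OE control 1 and OE Sirt1 2.

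The siRNA arrays asked which genes change when SIRT1 is lowered, with a pair of siRNAs as a guard against off-target effects. With KD1, interferon-stimulated genes fell. IFI27 fell to a log2 fold change of -1.65 (SE 0.18, limma adjusted p = 0.0135), 3.14-fold lower, and IFIT1, which binds viral RNA, to -1.61 (SE 0.16, adjusted p = 0.0134), 3.05-fold lower. IFITM1, which blocks virus entry, fell to -1.42, ISG15, a ubiquitin-like modifier, to -1.26, IFIT2 to -1.06 and the interferon signalling factor IRF9 to -0.77. Outside this list JPT1 (-1.12), HELZ2 (-1.01), the chaperone CANX (-0.94, and -0.96 at its other probe) and the tachykinin TAC3 (-0.94, detected on 1 of 2 KD1 arrays) fell. UBD, a ubiquitin-like modifier, rose 2.97-fold (+1.57, SE 0.23, adjusted p = 0.0444), and MYO1D (+0.86), MSRB3, a methionine sulfoxide reductase (+0.85), the collagen gene COL3A1 (+0.83) and RIDA (+0.66) rose with it. In all, 21 genes passed (5 higher, 16 lower), with folds of 1.58 to 3.14, and 1051 had an unadjusted p under 0.05. On the authors' normalised values 75 passed (21 higher, 54 lower), and with the trend and robust model 77 (24 higher, 53 lower). Of the 21, 11 also differed between the scrambled and vector controls in the opposite direction and 0 in the same direction, among them MYO1D (-0.85, scrambled minus vector), MSRB3 (-0.66) and RIDA (-0.39, but +0.01 at its other probe). The scrambled controls enter both comparisons with opposite signs, so error in these 2 arrays pushes the same way. The KD1 count fell to 0 without siRNA control 1, control 2 or KD1 replicate 1, to 1 gene (BIRC7) without KD1 replicate 2, and to 0 when the siRNA arrays were fitted alone. With replicate number as a block 3 genes passed, IFI27, IFIT1 and TNFSF10. With group means removed from each gene, same-numbered arrays gave r = -0.0214 across genes. With 2 arrays per group, every pair of a scrambled and a KD1 array gives this size, with either sign. The only same-numbered pair with KD2, siRNA control 2 and KD2 replicate 2, gave r = 0.147.

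By list, 5 of 43 passed with KD1. Type I interferon response genes fell: 6 of 25 tested members were lower over all genes and 18 lower adjusted over the list alone, with a median log2 fold change of -0.67 (camera adjusted p = 6.74e-20). Immediate early genes, which respond within minutes to growth factors, had 0 members past over all genes and 4 lower adjusted over the list alone, DUSP5 (-0.71), KLF4 (-0.67), EGR1 (-0.55) and JUND (-0.36), with a list adjusted p of 9.06e-05 and adjusted p = 0.298 with an estimated correlation. The scrambled controls scored high for this list, at 0.29 and 0.34, against -0.17 to -0.11 on the vector arrays and -0.19 and 0.10 with KD1. Its fall is thus opposite to a rise between the controls (mean +0.46, scrambled minus vector). The call of this list was lost without KD1 replicate 1 (0.0964). Drug-metabolising enzymes and transporters had 0 members past over all genes and 2 adjusted over the list alone, GSTA1 (-1.01) and ABCC3 (-0.56) (list adjusted p = 0.0252, adjusted p = 0.237 with an estimated correlation), and the call was lost without siRNA control 2 (0.0721) or KD1 replicate 2 (0.122). Epithelial-mesenchymal transition genes lay higher, with 0 members past over all genes and 3 adjusted over the list alone, ACTA2 (+0.83), TAGLN (+0.68) and VIM (+0.54) (0.0407, adjusted p = 0.446 with an estimated correlation); this was lost without siRNA control 2 (0.193) or KD1 replicate 2 (0.256) and with the replicate block (0.0676). Hypoxia response genes lay lower, with a median of -0.30 and 0 of 18 members past either way (0.0279, adjusted p = 0.754 with an estimated correlation). The hypoxia scores of the KD1 arrays were far apart, -0.01 and 1.28, and without KD1 replicate 1 the list's mean was +0.18 (adjusted p = 0.135), without control 1 the adjusted p was 0.125 and without control 2 it was 0.0651. Only the interferon call among all lists and comparisons held with an estimated correlation, with adjusted p = 0.0153 for KD1, 0.0398 for KD2 and 0.0138 for their mean. By fry 4 lists passed for KD1, 3 for KD2, 5 for their mean, 1 between the siRNAs, 13 between the controls and 0 for overexpression. Markers of cell types that a culture could hold did not pass as lists: fibroblast markers, of which COL3A1 is a member, gave adjusted p = 0.384 with KD1 and 0.443 with KD2, and leukocyte markers 0.225 and 0.546.

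With KD2 the interferon-stimulated genes again fell. IFI27 was 4.53-fold lower (-2.18, SE 0.18, limma adjusted p = 0.00178), IFIT1 2.78-fold lower (-1.47), OAS3, a sensor of double-stranded RNA, 2.69-fold lower (-1.43), IFITM1 2.54-fold lower (-1.35) and MX1, an antiviral GTPase, 2.51-fold lower (-1.33). The cell adhesion molecules CEACAM6 (-1.68, SE 0.23, adjusted p = 0.012) and CEACAM1 (-1.35, and -1.46 at its other probe) fell, as did the collagen receptor subunit ITGA2 (-1.50, SE 0.16, adjusted p = 0.00516). The scrambled arrays lay apart for CEACAM6, at 8.36 and 9.23, and leaving out 1 array gave it a log2 fold change of -2.11 to -1.25. IFRD2 fell to -1.26, and TAC3, not detected with KD2, was at least 1.86-fold lower. Among the higher genes were TULP3, a cilium transport factor (+1.21, SE 0.17, adjusted p = 0.0153), COL3A1 (+0.99), the peptidase MME (+0.93), TAF15, an RNA-binding protein (+0.90, and +1.07 at its other probe), AIDA (+0.89), the protease CTSZ (+0.88), carbonic anhydrase CA2 (+0.79) and KYNU, of tryptophan breakdown (+0.72). LINC01918 and SNORD76, not detected in the siRNA controls, were at least 1.41-fold and at least 1.62-fold higher. In all, 50 genes passed (12 higher, 38 lower), with folds of 1.59 to 4.53, and 1451 had an unadjusted p under 0.05. On the authors' normalised values 167 passed (45 higher, 122 lower), with the trend and robust model 172, and with the hypoxia covariate 126. Of the 50, 15 also differed between the scrambled and vector controls in the opposite direction and 0 in the same direction, among them TAF15 (-0.82, scrambled minus vector), TULP3 (-0.72), AIDA (-0.68), ITGA2 (+0.74) and CEACAM1 (+1.06). The KD2 count was 2 without siRNA control 1 (CEACAM6 and IFI27), 2 without control 2 (IFI27 and TMED10), 7 without KD2 replicate 3, and 1, IFI27, when the siRNA arrays were fitted alone.

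Of the lists, 2 of 43 passed with KD2. The type I interferon response fell, with 8 of 25 members lower over all genes and 15 lower adjusted over the list alone, at a median of -0.59 (camera adjusted p = 1.92e-14). The members with the smallest falls among the 8 were OAS1 (-1.03) and ISG15 (-1.10). DNA replication genes lay lower, at a median of -0.16 over 34 genes, 29 of them below 0, with 0 members past over all genes or adjusted over the list alone (adjusted p = 0.0177, adjusted p = 0.553 with an estimated correlation, fry 0.0146). The licensing factor CDT1 stood at -0.55, GINS2 at -0.47 and MCM3 at -0.36, against E2F1 at +0.85. That call was lost without siRNA control 1 (0.0753) or KD2 replicate 3 (0.158), and on the siRNA arrays alone (0.0529).

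Both siRNAs moved 10 genes past the threshold the same way, 2 higher and 8 lower, and 0 in opposite ways. Of these, 5 belong to the interferon list: averaged over both siRNAs (4 arrays against 2) IFI27 was 3.77-fold lower (-1.91, SE 0.16), IFIT1 2.91-fold (-1.54, SE 0.14), IFITM1 2.61-fold (-1.38, SE 0.17), ISG15 2.27-fold (-1.18, SE 0.17) and IFIT2 2.18-fold (-1.13, SE 0.11). The other lower genes were SIRT1, TAC3 (-1.13, detected on 1 of the 4 siRNA arrays against SIRT1, so its size is uncertain) and MTMR11 (-0.81), and the higher ones COL3A1 (+0.91, SE 0.11) and RIDA (+0.66, SE 0.09). Between the scrambled and vector controls 6 of the 10 differed in the opposite direction: IFI27, IFIT1, IFITM1, ISG15, MTMR11 (+0.92, scrambled minus vector) and RIDA. The other RIDA probe stood at +0.01 between the controls, and at +0.57 with KD1 and +1.31 with KD2 against the scrambled control. The controls did not pass for SIRT1 (+0.03), TAC3 (+0.14), IFIT2 (+0.19) or COL3A1 (-0.34). Independent lists of these sizes would share 0.00524 higher and 0.0531 lower genes. These figures take no account of the shared controls or of the variance per gene that both tests share. In 100 simulations of unchanged groups with the same shared controls 0 genes passed in both, but with no change simulated few genes pass at all, so that value says little. Of all genes 65.2% had the same sign with both siRNAs, against 65.3% to 67.6% in these simulations. Across all genes, which are not independent replicates, the log2 fold changes of the siRNAs had r = 0.482, against 0.478 to 0.522 in these simulations. The covariance of the log2 fold changes was 0.0362, above the simulated 0.0236 to 0.0277. The simulations drew each gene independently, and with 2 control arrays the controls could not be divided between the siRNAs. Part of the excess may therefore come from the shared controls. Each gene was also given the same SD in all groups. The scrambled arrays were closer to each other (r = 0.992) than the KD1 arrays (0.984) or the KD2 arrays (0.983). Where controls vary less than the siRNA groups, shared controls give a lower r and covariance than simulated. The simulated ranges therefore do not settle how alike the siRNAs are. For the mean of both siRNAs 3 lists passed: the interferon list (8 of 25 members lower over all genes, 18 adjusted over the list alone, camera adjusted p = 1.41e-20), immediate early genes (0 and 2 lower, 0.00122, adjusted p = 0.381 with an estimated correlation) and drug-metabolising genes (0 and 4 lower, 0.0194, adjusted p = 0.212 with an estimated correlation). The calls of the last pair were lost without siRNA control 2 (0.073 and 0.118). The number of shared genes was 0 without siRNA control 1, control 2, KD1 replicate 1 or KD1 replicate 2, and 5 without KD2 replicate 3 (IFI27, IFIT1, IFIT2, IGFBP6 and TNFSF10). It was also 0 when the siRNA arrays were fitted alone.

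**Figure D2:**
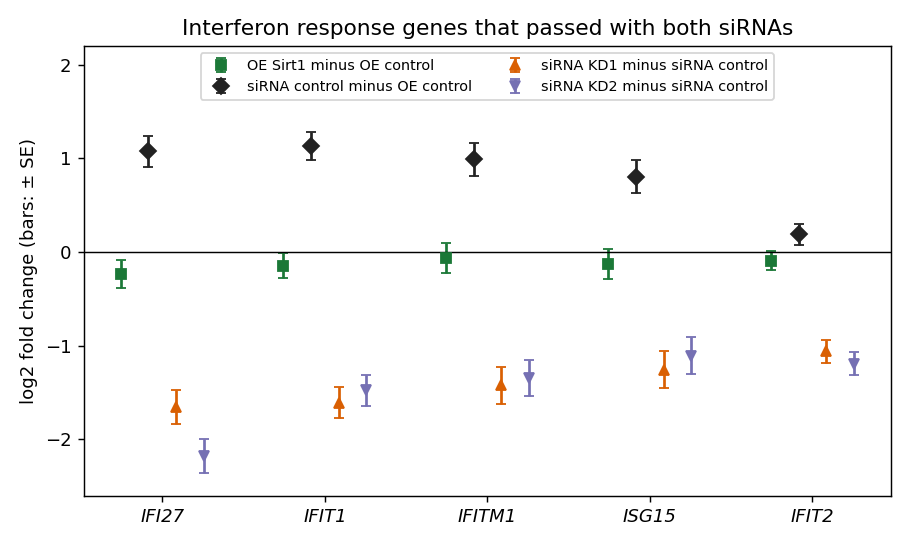
Log2 fold change with SE (y axis) of 5 interferon-stimulated genes in 4 comparisons (x axis groups). With KD1 and KD2 IFI27 lies at -1.65 and -2.18 against the siRNA control, and the siRNA control itself lies 1.07 above the vector control.

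The siRNAs also differed from each other. ITGA2 was higher with KD1 than with KD2 (+1.51, SE 0.16, limma adjusted p = 0.00773), as were the stem cell factor SOX2 (+1.27), UBD (+1.24), MSMB (+1.24) and the vesicle cargo receptor TMED10 (+1.23, SE 0.12, adjusted p = 0.00639). DYRK4, a kinase (-1.26), JPT1 (-1.09) and the cilium protein BBIP1 (-1.03) were lower with KD1, and LINC01918 and SNORD76, not detected with KD1, were at least 1.32-fold and 1.52-fold lower. In all, 75 genes passed (54 higher, 21 lower with KD1), and 1387 had an unadjusted p under 0.05. Of the 75, 6 also passed for KD1 and 19 for KD2 against the control. SIRT1 itself did not pass (-0.18, adjusted p = 0.794), nor did any interferon list member. DNA replication genes lay higher with KD1 at a mean of +0.25, with MCM2 at +0.61 (camera adjusted p = 3.27e-06, adjusted p = 0.152 with an estimated correlation, fry 0.00315). Hypoxia response genes (mean -0.51, 0.00277, adjusted p = 0.913 with an estimated correlation) and enterocyte differentiation genes (mean -0.26, 0.0438, adjusted p = 0.908 with an estimated correlation), with APOA4 at -1.43 and APOC3 at -0.78, lay lower. No member of these lists passed over all genes or adjusted over the list alone. The count between the siRNAs was 0 on the siRNA arrays alone, 1 without KD1 replicate 1 (ITGA2), 10 without KD1 replicate 2 and 0 without KD2 replicate 3. Without KD1 replicate 1 the hypoxia list turned upward (adjusted p = 0.54) and the enterocyte call was lost (0.439), and without KD2 replicate 3 both were lost (0.844 and 0.483).

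Overexpression and knockdown were set side by side to see which genes moved in opposite ways. No gene passed in both, in opposite or the same direction, and 0 genes passed the test of the difference between the effects by limma, with 922 at an unadjusted p under 0.05. Log2 fold changes of OE Sirt1 and of the mean siRNA effect had r = -0.0466 across genes. At an unadjusted p under 0.05 in both, 46 genes moved in opposite ways against 22.4 expected from independent lists, and 22 the same way against 20.4. Both effects were tested with the same variance for each gene, so the lists are not independent and the expected numbers are no firm baseline. Interferon response genes lay below 0 in both, for 84% of members with OE Sirt1 and 92% with the mean of the siRNAs.

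The scrambled siRNA and empty vector controls were compared as background, since each SIRT1 treatment has its own control. Genes that respond to low oxygen were far higher in the siRNA controls. ANKRD37 was 29.4-fold higher (+4.88, SE 0.56, limma adjusted p = 0.00554), LOX, a collagen cross-linking oxidase, 25.1-fold (+4.65), and beside them stood the water channel AQP10 17.3-fold (+4.11, detected on 2 of 3 vector arrays), and the glycolytic enzyme ENO2, not detected in the vector arrays, at least 12.7-fold. PPP1R3C, of glycogen storage, was at least 4.65-fold higher. The metallothionein MT4 (-1.68, SE 0.17, adjusted p = 0.00468), the antimicrobial lectin REG3A (-1.17), topoisomerase TOP1 (-1.16, but -0.24 at its other probe), JADE2 (-1.12) and TENM4 (-1.08) were lower. In all, 578 genes passed, 435 higher and 143 lower, and on the authors' normalised values 673 were higher and 384 lower. Of 18 hypoxia response genes 16 rose over all genes and 17 adjusted over the list alone, with a median of +1.81 (camera adjusted p = 1.35e-17, adjusted p = 0.328 with an estimated correlation). Glycolysis genes rose, 7 of 19 over all genes and 14 adjusted over the list alone, with HK2 at +2.00, ALDOC at +2.07 and PGK1 at +1.02 (2.90e-08, adjusted p = 0.372 with an estimated correlation). Interferon response genes rose too, 8 of 25 over all genes and 9 adjusted over the list alone, with ISG20 at +1.55 and IFIT1 at +1.13 (0.000111, adjusted p = 0.281 with an estimated correlation). The count was 179, 205 and 137 without OE control 1, 2 and 3, 4 without siRNA control 1 (ALOX5AP, BRWD3, MT4 and SLC39A2) and 0 without siRNA control 2. The controls differ in nucleic acid and in any batch that goes with it, which cannot be told apart.

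**Figure D3:**
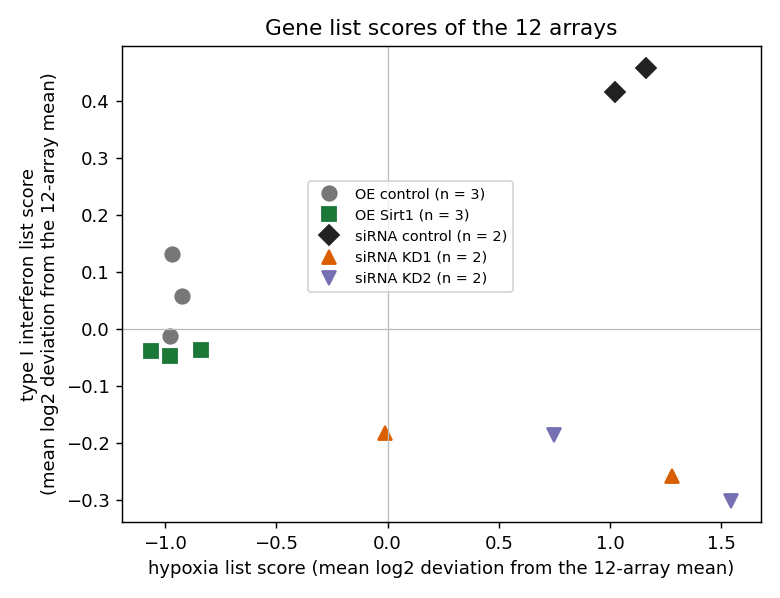
Hypoxia score (x axis, log2) and interferon score (y axis, log2) of each of the 12 arrays, by group. Hypoxia scores of the 6 plasmid arrays lie at or below -0.84, and KD1 replicate 1 lies at -0.01, apart from the 5 other siRNA arrays.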

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

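The tests of explanations given here were chosen after the results they measure had been seen, except 3 of the 4 scalings of the hypoxia list (the scaling without quantiles was added later) and the splits of the overexpression arrays by gene lists, which were set beforehand.

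The siRNAs against SIRT1 differed from each other in 75 genes. In log2 KD1 minus KD2, ITGA2 stood at 1.51, SOX2 at 1.27, UBD at 1.24, MSMB at 1.24, TMED10 at 1.23, IFRD2 at 1.12 and MSRB3 at 0.94. CANX stood at -0.75, BBIP1 at -1.03, JPT1 at -1.09 and DYRK4 at -1.26. SNORD76 and LINC01918 were not detected with KD1, so their fitted values of -1.20 and -1.25 are no measure of size, and they were at least 1.52-fold and 1.32-fold lower. By list, the mean difference was -0.51 for hypoxia response (adjusted p = 0.913 with an estimated correlation), 0.25 for DNA replication (0.152) and -0.26 for enterocyte differentiation genes (0.908). The KD1 arrays scored -0.01 and 1.28 for hypoxia, and the hypoxia difference turned to 0.13 without KD1 replicate 1 and was -0.11 without KD2 replicate 3, while the enterocyte call was lost without either (adjusted p = 0.439 and 0.483). Among the 4159 detected probes without a single gene name, which no comparison above used, 16 passed with KD2 (7 higher, 9 lower), 3 with the mean of the siRNAs, 8 between the siRNAs and 61 between the controls.

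Interferon response genes were lower with both siRNAs than with the scrambled control, by a list difference of -0.67 (SE 0.05). A culture state that the hypoxia score tracks is argued against as the whole cause, since the difference was -0.68 (SE 0.04) with that score as a covariate. A high level in the scrambled control arrays stays open, and 4 of the 5 shared interferon genes differed between the controls too: the control scored 0.38 (SE 0.05) above the vector control, yet the knockdown arrays also scored -0.29 relative to the vector control, and the vector arrays differ from these in transfection as well. Lower SIRT1 also stays open, because overexpression gave -0.10 (SE 0.04) on arrays where the SIRT1 probe was not raised. Which of these may account for the difference cannot be told apart here.

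Hypoxia response genes scored higher on each of the 6 siRNA arrays than on any plasmid array, and were uneven within KD1 and, less so, within KD2. The scores of the KD2 arrays were 0.75 and 1.55, while the range was 0.06 to 0.22 within the control and OE Sirt1 groups. Normalization is argued against for the difference between the controls: the list's lowest median over 4 other scalings was 1.51 against 1.81, with 18 of 18 members higher in each. An array without SIRT1 siRNA in the place of KD1 replicate 1 is argued against by its SIRT1 level of 7.31, below the lowest of the 8 arrays without SIRT1 siRNA (8.49, range 0.45). A culture or harvest batch stays open, with a score range of 1.29 between the KD1 arrays, 0.80 between the KD2 arrays and no batch in the labels. Transfected nucleic acid goes with the same arrays and is also untested.

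No gene passed between OE Sirt1 and OE control. A SIRT1 probe outside the transfected sequence could explain the SIRT1 value of -0.00311 but stays open, since the probe's place is not known here. These arrays therefore do not show whether the plasmid raised SIRT1, and the count of 0 genes cannot be read as the response to raised SIRT1. With 3 arrays against 3 only 10 splits exist, too few for a share under 0.05. For genes the real count of 0 is met by all 10 splits by construction (highest other 0), so they decide nothing, and for lists 2 splits gave as many (real 1, highest other 1). At an unadjusted p under 0.05 the real split gave 407 genes. The splits that kept OE control 1 with OE Sirt1 2 gave 554 to 811 genes. The other splits, the real one included, gave 318 to 408. OE control 1 and OE Sirt1 2 were each other's nearest array (r = 0.989), and with group means removed they had r = 0.226 across genes. This points to a structure among the arrays that crosses the vector and OE Sirt1 groups. Its source, and whether it hid effects of the plasmid, was not tested.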

How the results depend on the processing

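The hypoxia covariate and a scaling without quantiles, used for the hypoxia list alone, were chosen after the data had been seen. Signal over background limits genes detected on few arrays, and a left-out array leaves siRNA groups with 1 array, assumed to vary like the others. The cause was not tested for the changes below, except that no filter tests more genes and fewer arrays give fewer degrees of freedom. A fit on fewer arrays also takes its variance from those arrays alone, and these effects cannot be told apart. The series value table equals the deposited normalised table and no slide is named, so neither alternative was run. The replicate block was run for overexpression and KD1; KD2 shares 1 number with its control. Separate normalization and each experiment's arrays alone give no value between the controls.

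On the authors' normalised table the counts were 75 (KD1), 167 (KD2), 162 (KD1 against KD2), 1057 (controls) and 23 (shared by both siRNAs). Without background correction they were 66, 159, 134, 990 and 24, and with normexp 54 (KD1), 114 (KD2), 878 (controls) and 20 (shared). With the trend and robust model they were 77, 172, 163, 1011 and 23. Without a filter they were 4 (KD1: CIAO2A, IFI27, IFIT1 and IFIT2), 303 (controls) and 3 (shared: IFI27, IFIT1 and IFIT2). On the siRNA arrays alone they were 0 (KD1), 1 (KD2), 0 (KD1 against KD2) and 0 (shared). With all probes KD1 gave 7 and the shared count was 4 (IFI27, IFIT1, IFIT2 and IFITM1), with the replicate block KD1 gave 3, and with the hypoxia covariate KD2 gave 126. Leaving out 1 array gave 0 to 1 for overexpression, 0 to 1 for KD1, 2 to 50 for KD2, 0 to 68 between the siRNAs, 0 to 205 between the controls and 0 to 8 shared.

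SIRT1 in KD1 no longer passed without a filter (-1.39, adjusted p = 0.0695), on the siRNA arrays alone (-1.39, 0.434), with the replicate block (-1.39, 0.12), with the hypoxia covariate (-1.51, 0.0577) or with 1 array left out (-1.54 to -1.24); its adjusted p ran from 0.0015 to 0.434 over alternatives. SIRT1 in KD2 no longer passed without a filter (-1.20, 0.0735) or on the siRNA arrays alone (-1.20, 0.274), and leaving out 1 array gave -1.55 to -0.86; its adjusted p ran from 0.00237 to 0.299. With overexpression the SIRT1 value changed sign in 3 of 6 left-out fits, over a range of -0.0866 to 0.137, at adjusted p = 1.

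For lists, overexpression gave 0 without a filter, with an estimated correlation and by fry, and 0 to 1 with 1 array left out. KD1 gave 1 with an estimated correlation and 2 to 8 with 1 array left out. KD2 gave 4 on the authors' table, 4 without background correction, 1 on the siRNA arrays alone, 1 with an estimated correlation and 1 to 7 with 1 array left out. The correlation of the siRNA effects ran from 0.303 to 0.603 and that of overexpression with knockdown from -0.0718 to -0.0169. None of the genes named by rule for a comparison, SIRT1 apart, changed direction there under the alternatives run; members named for a list alone were not followed gene by gene.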

Other observations

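The hypothesis of opposite movement arose after its gene counts had been seen, its test on splits was set before the splits were run, and the other comparisons were fixed beforehand.

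In lists other than those described above, the scrambled siRNA controls differed from the vector controls in rapid-response and daily-rhythm genes, among others. Whether the members of these lists rose apart from the response to low oxygen was not tested. Immediate early genes rose in 7 of 16 members over all genes (9 higher and 2 lower adjusted over the list alone), with FOS at +2.53 and ZFP36, which destabilises mRNA, at +1.37 (camera adjusted p = 0.00147, adjusted p = 0.342 with an estimated correlation). This list lay lower with KD1 and with the mean of both siRNAs, and the same scrambled controls enter those comparisons with the opposite sign. Circadian clock genes rose in 5 of 15 members over all genes and 5 adjusted over the list alone, among them the repressor BHLHE40 at +1.69 and DBP at +0.76 (0.00579, adjusted p = 0.281 with an estimated correlation). FOXO target genes rose in 3 of 13 over all genes and 6 adjusted over the list alone, with CITED2 at +1.17 (0.00303, adjusted p = 0.281 with an estimated correlation). Amino acid stress genes rose in 2 of 21 over all genes and 5 adjusted over the list alone, with VLDLR at +1.19 (0.0116, adjusted p = 0.47 with an estimated correlation).

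Another 7 lists lay lower in the siRNA controls. Ribosome biogenesis genes had a median of -0.32, with 1 of 23 lower over all genes and 1 adjusted over the list alone, NOP56 at -0.52 (0.000507, adjusted p = 0.459 with an estimated correlation). Proteasome genes had a median of -0.20, with 1 of 24 lower over all genes and 2 adjusted over the list alone, among them PSMC3 at -0.56 (0.0015, adjusted p = 0.459 with an estimated correlation), and heat shock genes had a median of -0.13, with 1 of 18 lower either way, the cochaperone FKBP4 at -0.64 (0.0131, adjusted p = 0.47 with an estimated correlation). Spliceosome (0.000974), mitosis (0.023), DNA replication (0.0404) and Wnt target genes (0.0441) lay lower with 0 members past over all genes or adjusted over the list alone, and with an estimated correlation their adjusted p values ran from 0.303 to 0.521. The mitosis call was lost without OE control 3 (0.054) or siRNA control 1 (0.191), the replication call without OE control 1 (0.0747), OE control 2 (0.0675) or siRNA control 2 (0.103), and the Wnt call without OE control 1 (0.0747), OE control 3 (0.069), siRNA control 1 (0.0789) or siRNA control 2 (0.0711).

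A hypothesis was that overexpression and knockdown move some genes in opposite ways, since 46 genes did so at an unadjusted p under 0.05 and 22 moved the same way, a difference of 24. Over the 10 splits of the 6 overexpression arrays 1 split, the real one, gave a difference as large; sizes were taken without sign, since the sides of a split have no order. The highest other was 21, from 9 opposite and 30 same-way genes as coded. With 10 splits no share under 0.05 can arise, so the test leaves the hypothesis open.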
